A study of Mus musculus with 21 samples.

How the data were processed

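Sorted DCs of an Aire-reporter strain were sequenced in 21 libraries, 12 from lymph node in 4 groups and 9 from bone marrow in 3 groups, with 3 independent biological replicates per group. Per the labels the mice were male C57BL/6 of 6 weeks, lymph node cells were gated as CD45+CD11c+MHCII+ and split by the reporter, and bone marrow AGF+ cells came from the B220−CD24+ fraction low in or without CD11b. Per the submitters' processing notes 1 ng of RNA with an integrity number above 7 was made into Ovation SoLo libraries and read paired-end at 150 bp. The notes name fastp 0.20.0, STAR 2.7.3a, SAMtools 1.9, Picard 2.21.1, HTSeq 0.11.2 and edgeR 3.38.1 on mm10. The annotation release, the strand setting and the handling of reads that map to several genes are not given in the sources used here.

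The deposited raw table holds read counts (unit: counts) for 55471 genes, of which 327 with 0.0139% of counts matched no symbol of GENCODE vM21. The deposited normalized table (unit: signal) holds 17265 genes and equals the counts times 1 factor per library, to a relative deviation of at most 5.1e-15, as edgeR gives with its expression filter and TMM over all libraries. All values and tests here were computed from the counts, and CPM uses TMM effective library sizes, which were 0.874 to 1.09 of the totals. No library was left out. Totals of 4164451 to 6055097 counts per library are shallow, so a gene at 1 CPM rests on 3.91 to 6.56 counts in a library.

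Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM, expression filter by group, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. The lymph node comparisons came from 1 fit of its 12 libraries and the bone marrow comparisons from 1 fit of its 9, while comparisons between the tissues used all 21. Comparisons were AGF+ with AGF− cells in each genotype, AireKO with KI/+ cells in each sort, bone marrow AGF+ cells with total DCs, AGF+ cells of the tissues, and the interactions of genotype with sort and with tissue. Before the data were examined, 33 gene lists covering DC subsets and states, other cell types, antigen presentation, signalling and metabolism were fixed. They were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry, when at least 3 members passed the filter. Counts adjusted over the list alone use only the members of that list.

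Genes named in the text follow a rule set before the data were examined. It takes Aire, and the 8 largest rises and 8 largest falls among genes with adjusted p under 0.05, a change of at least 2-fold, an average log2 CPM of at least 3 and replicates that do not overlap, without predicted genes, pseudogenes and antigen receptor segments. It adds up to 4 members of each described list with the smallest adjusted p (ties were broken by p when the text was written), and all calls of a comparison with fewer than 10. Genes outside the rule are said to be chosen after their values were seen. Of the genes the rule names, 2 are not reported here.

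Replicate numbers were checked as pairs before calls were compared. Deviations of libraries with the same number from their group means correlated above 0.1 for every number in 7 of 9 group pairs within a tissue, including all pairs compared there, and in 5 of 12 across tissues. The number was therefore tried as a block within tissues. Alternatives set before the data were examined were DESeq2 1.42.0 size factors, library size alone, no filter on low counts, at least 10 counts in at least 3 libraries, the DESeq2 Wald test, limma voom with sample weights, fits of only the groups compared or of all libraries, the replicate block, a test against a 1.5-fold change (glmTreat), an adjusted p under 0.01, and each library left out. The replicate block for lists, offsets for gene length and GC content, and the fit without the libraries numbered 2 were added after the data were examined. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

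The tests were tested on simulated counts in which 100 genes changed 2-fold and 100 changed 4-fold. Of these, 71 and 99 were recovered in the layout of the lymph node reporter comparison with 6 false calls, 69 and 99 with 18 false calls for genotype in lymph node AGF+ cells, 70 and 99 with 8 for genotype in bone marrow, 35 and 90 with 6 for the interaction with sort, and 40 and 97 with 3 for the interaction with tissue. A simulated list of 20 genes shifted 1.5-fold was called by camera (adjusted p = 1.6e-31) and 0 unshifted lists were. Every gene and library was drawn independently in these simulations. They therefore tell nothing about false calls among lists of correlated genes.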

Results

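Gene expression was measured by RNA sequencing in dendritic cells (DCs) sorted from mice that carry a reporter knock-in allele, AGF-KI, for Aire, the autoimmune regulator, a transcriptional regulator best known from the medullary thymic epithelium. The 21 libraries fall into 7 groups of 3 biological replicates. Lymph node DCs were sorted by the reporter into AGF+ and AGF− cells, each from AGF-KI/+ mice (KI/+) and from AGF-KI/- mice, which the labels name AireKO. Bone marrow gave AGF+ cells of both genotypes and, from KI/+ mice only, a second DC population that the titles call total DC and the design text calls AGF−. It is named total DC here. Each library held 4164451 to 6055097 counts, so that a count of 0 in a library allows at most 0.458 to 0.767 CPM over effective library sizes. Over all libraries the first principal component, with 50.1% of the variance, separated lymph node from bone marrow, and no pair of replicates was as close as counting noise alone (chi-square per degree of freedom 4.46 to 20.3 over 21 pairs). Fold changes given as at least N-fold, or with a counting interval, rest on groups of 3 libraries with 0 or 1 to 3 counts in all, and such floors and intervals cover counting error only. Unless stated otherwise, levels are mean CPM ± SD of 3 libraries, and log2 fold changes are given ± SE from 3 libraries against 3.

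Aire was highest in the AGF+ cells of KI/+ mice and lower in those of AireKO mice in both tissues. In lymph node AGF+ cells it stood at 132, 99.0 and 112 CPM in the KI/+ libraries (mean 114 ± 16.7) and at 22.8, 26.6 and 26.3 CPM in the AireKO libraries (25.2 ± 2.10). Bone marrow AGF+ cells had 116, 109 and 79.6 CPM in KI/+ (101 ± 19.2) against 11.5, 12.4 and 19.7 CPM in AireKO (14.5 ± 4.48). Lymph node AGF− cells held 14.9, 14.2 and 14 CPM in KI/+ and 10.5, 14.2 and 13.3 CPM in AireKO, means of 14.4 ± 0.488 and 12.7 ± 1.93. Bone marrow total DCs were near 1.28, 0.822 and 0.968 CPM (1.02 ± 0.236). Between genotypes Aire fell by 2.19 ± 0.15 on the log2 scale in lymph node AGF+ cells (adjusted p = 8.6e-06) and fell by 2.81 ± 0.22 in bone marrow AGF+ cells (adjusted p = 3.5e-04), and every AireKO library lay below every KI/+ library. In lymph node AGF− cells its change did not pass the test (-0.19 ± 0.16, 95% interval -0.55 to 0.16, adjusted p = 0.883). Transcripts counted to Aire thus remained in the AireKO libraries, and which part of the gene each allele lacks is not given in the sources used here.

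Dnmt3l, which encodes a catalytically inactive cofactor of the de novo DNA methyltransferases, rose in AireKO cells of every sort tested. It went from 9.02 ± 0.715 CPM in KI/+ to 60.5 ± 9.50 CPM in AireKO lymph node AGF+ cells, from 0.361 ± 0.327 to 13.5 ± 3.09 CPM in AGF− cells and from 8.30 ± 0.311 to 103 ± 31.3 CPM in bone marrow AGF+ cells. Both genes lie on chromosome 10 of GRCm38 on opposite strands and overlap at their 5′ ends. Aire (ENSMUSG00000000731) spans 78030022 to 78043610 on the minus strand and Dnmt3l (ENSMUSG00000000730) 78041947 to 78063622 on the plus strand. Their exons share the 67 bases from 78042061 to 78042127, which are 2.24% of the exon bases of Dnmt3l. How reads in the shared part were assigned, and whether strand was used, is not given in the sources used here, so levels of both genes carry that uncertainty.

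**Figure D1:**
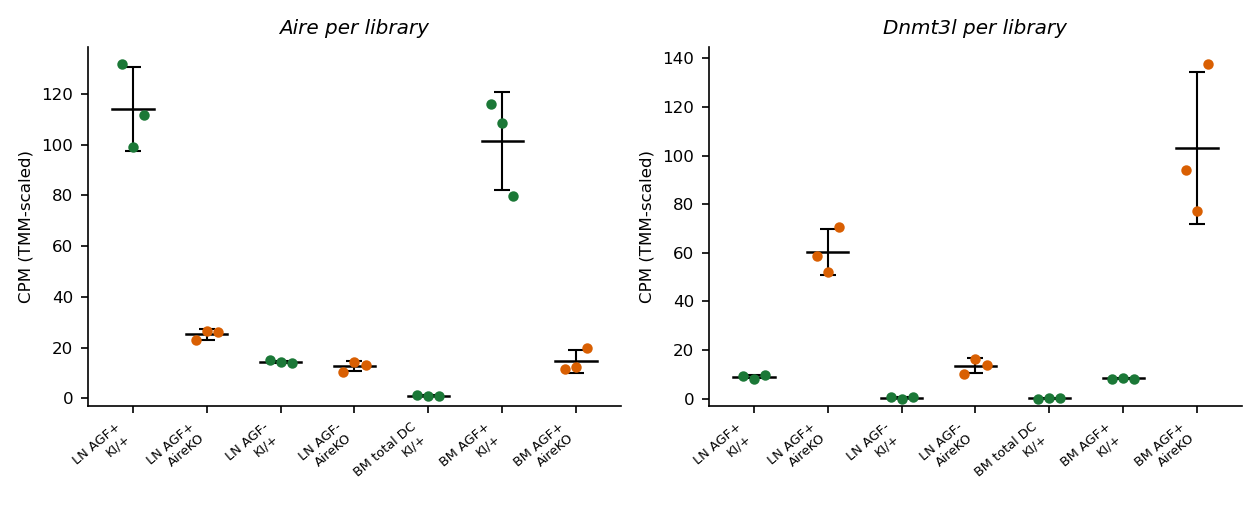
CPM of Aire and of Dnmt3l on linear axes in the 7 groups: each point is 1 library (green, KI/+, orange, AireKO) and bars with whiskers are the mean ± SD of 3 libraries. Aire drops from 114 to 25.2 CPM in lymph node AGF+ cells while Dnmt3l goes from 9.02 to 60.5 CPM.

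**Figure D2:**
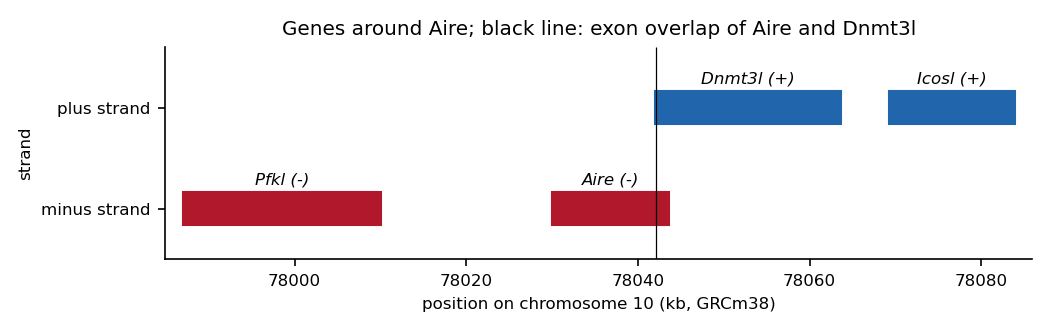
Map of the Aire locus on chromosome 10 (GRCm38, position in kb on the x axis): bars are the extents of Pfkl, Aire, Dnmt3l and Icosl with their strands, and the black line marks where exons of Aire and Dnmt3l overlap. The overlap of 67 bases lies at the 5′ ends of both genes.

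The labels give male mice throughout, yet the sex-linked transcripts split the libraries. In all 7 libraries numbered 2, 1 per group, Xist, the RNA that coats the inactive X chromosome, stood at 2028 to 4008 CPM, and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together reached only 0 to 0.768 CPM. The other 14 libraries had 0 to 31.2 CPM of Xist and 331 to 568 CPM over the 4 Y-linked genes. Each group holds 1 such library, so the split is balanced over all comparisons. These genes were chosen after their values were seen. Counts without the libraries numbered 2 are given where they move by over 1.5 times.

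**Figure D3:**
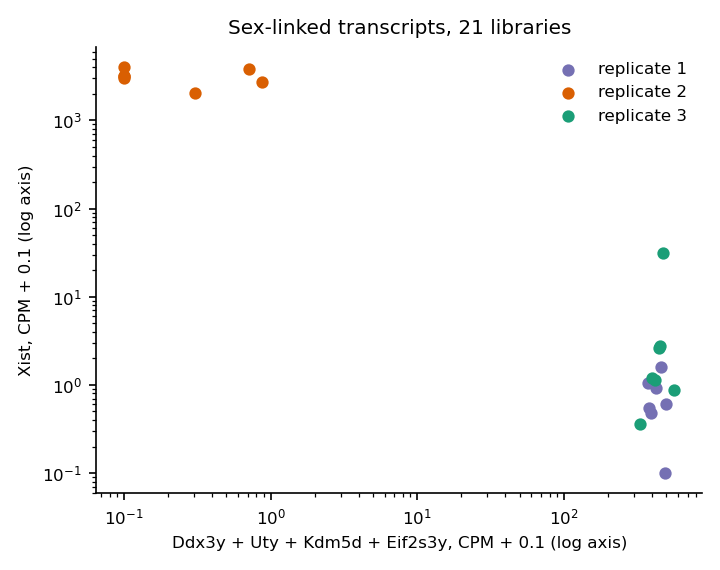
Xist (y axis) against the sum of Ddx3y, Uty, Kdm5d and Eif2s3y (x axis), both as CPM + 0.1 on log axes, with 1 point per library coloured by replicate number. The 7 libraries numbered 2 lie at 2028 CPM of Xist or more and at 0.768 CPM of Y-linked transcripts or less.

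To describe what sets Aire-reporter cells apart from other DCs of the lymph node, AGF+ cells were compared with AGF− cells of KI/+ mice. Among the largest rises were Ache (log2 fold change 6.02 ± 0.51), acetylcholinesterase, and Slc7a10, a neutral amino acid transporter that was 95.4-fold (counting interval 32.4 to 465) higher. Mdk (log2 fold change 5.11 ± 0.51), Pappa2 (3.84 ± 0.39), Ephb4 (3.83 ± 0.31) and Lhfpl2 (4.04 ± 0.70) rose as well. They encode a heparin-binding growth factor, a metalloproteinase of the insulin-like growth factor axis, an ephrin receptor and a tetraspan membrane protein. Aire itself, whose reporter defined the sort, rose by 2.99 ± 0.16 and its overlapping neighbour Dnmt3l by 4.58 ± 0.44. Icosl, the ligand of ICOS, which lies next to Dnmt3l, rose by 1.57 ± 0.22. In the list of Aire locus neighbours 2 of 15 measured members rose and 3 fell (2 rose when adjusted over the list alone). The list as a whole did not pass. Aire locus neighbours had camera adjusted p = 0.646, and adjusted p = 0.859 with an estimated correlation.

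Markers of T and NK cells, B cells and monocytes were lower in AGF+ than in AGF− cells, although none of these 3 lists passed with an estimated correlation. Among markers of T and NK cells 15 of 18 measured members fell and 1 rose (16 fell when adjusted over the list alone), led by Ncr1, an activating NK receptor (at least 159-fold lower), Klrb1c (333-fold, counting interval 59.2 to 13196) and Nkg7 (log2 fold change -6.39 ± 0.96). T and NK cell markers had camera adjusted p = 1.2e-06, and adjusted p = 0.388 with an estimated correlation. Granzyme B, Gzmb, was at least 53.4-fold lower. Gzma, 651-fold (counting interval 116 to 25760) lower, and Cd163l1 (-6.16 ± 1.21) lost their calls with limma voom (adjusted p = 0.0771 and 0.181). Klrc1, an inhibitory NK receptor whose reads can be shared with its close paralog Klrc2, and Klk1, of the kallikrein family, were 286-fold (counting interval 50.8 to 11346) and 87.9-fold (counting interval 29.7 to 429.8) lower. Of the B cell markers 13 of 15 measured members fell (15 fell when adjusted over the list alone), among them Blk (log2 fold change -5.73 ± 0.46), Fcrla (-5.04 ± 0.36) and Cd22 (-2.78 ± 0.29). B cell markers had camera adjusted p = 3.4e-27, and adjusted p = 0.0761 with an estimated correlation. Immunoglobulin and T cell receptor genes took 0.0177 ± 0.00239% of counts in AGF+ and 0.151 ± 0.0354% in AGF− cells. Monocyte and macrophage markers showed the same direction: 11 of 19 measured members fell (16 fell when adjusted over the list alone), with Ly6c2 (log2 fold change -5.90 ± 0.72), Ccr2 (-4.65 ± 0.43) and Lyz2 (-2.26 ± 0.23). Monocyte and macrophage markers had camera adjusted p = 2.5e-10, and adjusted p = 0.170 with an estimated correlation. Reads of Lyz2 can be shared with its near copy Lyz1. Not all lists of other leukocytes passed: of the genes of group 3 innate lymphoid cells 5 of 12 measured members fell and 2 rose (6 fell when adjusted over the list alone). Innate lymphoid genes had camera adjusted p = 0.819, and adjusted p = 0.975 with an estimated correlation.

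The markers of conventional DC subsets were lower in AGF+ cells too. For cDC1 cells, which take up dead cells and cross-present, 13 of 18 measured members fell (13 fell when adjusted over the list alone), including Clec9a (log2 fold change -3.95 ± 0.38), Xcr1 (-2.69 ± 0.34) and Naaa (-2.41 ± 0.21). Markers of cDC1 cells had camera adjusted p = 1.6e-09, and adjusted p = 0.117 with an estimated correlation. For cDC2 cells 10 of 16 measured members fell and 1 rose (10 fell when adjusted over the list alone): Cd209a (log2 fold change -4.89 ± 0.37), Clec4a2 (-3.06 ± 0.29) and Clec10a (-2.71 ± 0.28) fell and Esam (log2 fold change 1.93 ± 0.20) rose. Markers of cDC2 cells had camera adjusted p = 9.6e-07, and adjusted p = 0.0253 with an estimated correlation. Cd209a is open to reads of its paralogs. Of the plasmacytoid DC markers 8 of 16 measured members fell and 1 rose (11 fell when adjusted over the list alone), among them Ly6d (log2 fold change -4.85 ± 0.42) and Lifr (-2.20 ± 0.34). Plasmacytoid DC genes had camera adjusted p = 5.1e-06, and adjusted p = 0.388 with an estimated correlation. Genes of the mature, Ccr7-expressing DC state did not part the sorts as a group: 3 of 32 measured members rose and 2 fell (3 rose when adjusted over the list alone), with Ebi3 (log2 fold change 1.19 ± 0.22) up and Apol7c (log2 fold change -1.28 ± 0.32) down. Mature DC genes had camera adjusted p = 0.819, and adjusted p = 0.976 with an estimated correlation.

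Of the functional groups, chemokines and their receptors were lower in AGF+ cells: 12 of 23 measured members fell (17 fell when adjusted over the list alone), led by Ccl9 (log2 fold change -2.55 ± 0.18) and Ccl6 (-2.24 ± 0.27). Chemokines and receptors had camera adjusted p = 1.3e-11, and adjusted p = 0.0148 with an estimated correlation. Innate sensors followed, where 8 of 25 measured members fell and 2 rose (8 fell when adjusted over the list alone), with Tlr8 (log2 fold change -3.60 ± 0.40) and Tlr7 (-2.79 ± 0.32). Innate sensors had camera adjusted p = 7.3e-04, and adjusted p = 0.262 with an estimated correlation. Of the cell cycle genes 19 of 26 measured members fell (23 fell when adjusted over the list alone), for example Ccnb2 (log2 fold change -2.33 ± 0.29), Mki67 (-1.69 ± 0.21) and Top2a (-1.58 ± 0.19). Cell cycle genes had camera adjusted p = 9.8e-13, and adjusted p = 0.0761 with an estimated correlation. In the interferon response 9 of 24 measured members fell (14 fell when adjusted over the list alone), among them Irf7 (log2 fold change -1.35 ± 0.27) and Cmpk2 (-1.32 ± 0.20). Interferon response genes had camera adjusted p = 5.1e-06, and adjusted p = 0.359 with an estimated correlation. Of the genes of antigen presentation on MHC class II 6 of 16 measured members fell and 1 rose (8 fell when adjusted over the list alone): March1 (log2 fold change -1.75 ± 0.17), a ubiquitin ligase that removes MHC class II from the surface, and Cd74 (log2 fold change -0.63 ± 0.12), the invariant chain, fell and H2-DMb2 (log2 fold change 0.88 ± 0.15) rose. MHC class II genes had camera adjusted p = 0.0550, and adjusted p = 0.534 with an estimated correlation. Of the genes of eosinophils, basophils and mast cells 2 of 4 measured members rose and 2 fell (2 rose when adjusted over the list alone), with Prg2 (log2 fold change 3.60 ± 0.53) and Siglecf (2.16 ± 0.29) up and Ear2 (log2 fold change -2.97 ± 0.52) down. Eosinophil, basophil and mast cell genes had camera adjusted p = 0.676, and adjusted p = 0.750 with an estimated correlation.

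In all, 1603 genes were higher and 1746 lower in AGF+ cells of KI/+ mice out of 15884 tested (edgeR quasi-likelihood, adjusted p under 0.05), 894 and 942 of them at least 2-fold. The replicate values of the 2 sorts did not overlap for 38.4% of genes, where chance gives 10% for independent libraries. Mitochondrially encoded genes were lower in AGF+ cells of KI/+ mice, where 4 of 7 measured members fell (7 fell when adjusted over the list alone). Mitochondrial genes had camera adjusted p = 0.00927, and adjusted p = 0.534 with an estimated correlation. They took 1.19 ± 0.183% of counts in AGF+ and 1.88 ± 0.374% in AGF− cells. The named genes passed at adjusted p of at most 0.0108 (Apol7c). Camera called 14 of 31 lists, all lower in AGF+ cells, and 2 of them, cDC2 and chemokines, remained with an estimated correlation. Fry called 16 lists. Without the libraries numbered 2 the count was 1942 genes in place of 3349. Which direction held more genes depended on the scaling: 1782 were higher and 1548 lower with library size alone, and 2002 and 1787 with offsets for gene length and GC content, added after the data were examined.

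AGF+ and AGF− cells of AireKO mice differed in the same way. Ache (log2 fold change 6.16 ± 0.51) and Ephb4 (4.16 ± 0.31) rose again and Slc7a10 was 171-fold (counting interval 47.0 to 1420) higher. Among the largest rises were also Ntn5 (log2 fold change 4.90 ± 0.58), a netrin, Rimkla (log2 fold change 4.54 ± 0.47), an enzyme of N-acetylaspartylglutamate synthesis, Sema3f (log2 fold change 4.10 ± 0.47), a semaphorin, and Tcte1 (log2 fold change 4.13 ± 0.25), of the ciliary dynein regulatory complex. Aire rose by 0.99 ± 0.16 (adjusted p = 4.2e-04) between these sorts. Among the largest falls, Gzmb was at least 112-fold lower, Klrc1 416-fold (counting interval 74.3 to 16478) and Klrc2 279-fold (counting interval 49.7 to 11062), and Ncr1 (log2 fold change -7.45 ± 1.26), Ace (-7.23 ± 0.77) and Nkg7 (-6.94 ± 0.94) fell. Ace encodes the angiotensin-converting enzyme. Cd163l1 (575-fold, counting interval 159 to 4751) and Gzma (284-fold, counting interval 96.7 to 1378) were lower but lost their calls with limma voom (adjusted p = 0.0713 and 0.0750). All 15 measured B cell markers fell (15 adjusted over the list alone, camera adjusted p = 4.7e-29, adjusted p = 0.0688 with an estimated correlation), as did 11 of 16 cDC2 markers while 1, Esam, rose (11 fell adjusted over the list alone, camera adjusted p = 1.4e-08, adjusted p = 0.0210 with an estimated correlation). Of the chemokines and receptors 14 of 23 measured members fell (16 fell when adjusted over the list alone), with Ccr2 (log2 fold change -6.21 ± 0.48) and Cxcr3 (-4.84 ± 0.60). Chemokines and receptors had camera adjusted p = 8.1e-11, and adjusted p = 0.0168 with an estimated correlation.

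Of 15884 genes, 1812 were higher and 2114 lower in AireKO AGF+ cells, 994 and 1177 at least 2-fold, and 39.6% of genes did not overlap between the sorts (chance 10%). With the length and GC offsets 2304 were higher and 2125 lower. Both genotypes called 1226 genes higher, where independent lists give 183, and 1463 lower, where they give 232. The 2 comparisons share no library. Fold changes of the genotypes correlated across 11012 genes (r = 0.95, rho = 0.88), which are not independent replicates. Fry called 17 of 31 lists. Camera called 16, 1 higher and 15 lower, of which cDC2 and chemokines remained with an estimated correlation. The 1 higher list was NF-kB, where 4 of 21 measured members rose (4 rose when adjusted over the list alone). NF-kB genes had camera adjusted p = 0.0387, and adjusted p = 0.663 with an estimated correlation. Of the mitochondrially encoded genes 0 of 7 fell (0 adjusted over the list alone, camera adjusted p = 0.124, adjusted p = 0.711 with an estimated correlation), with 1.53 ± 0.0724% of counts in AGF+ and 1.86 ± 0.288% in AGF− cells.

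**Figure D4:**
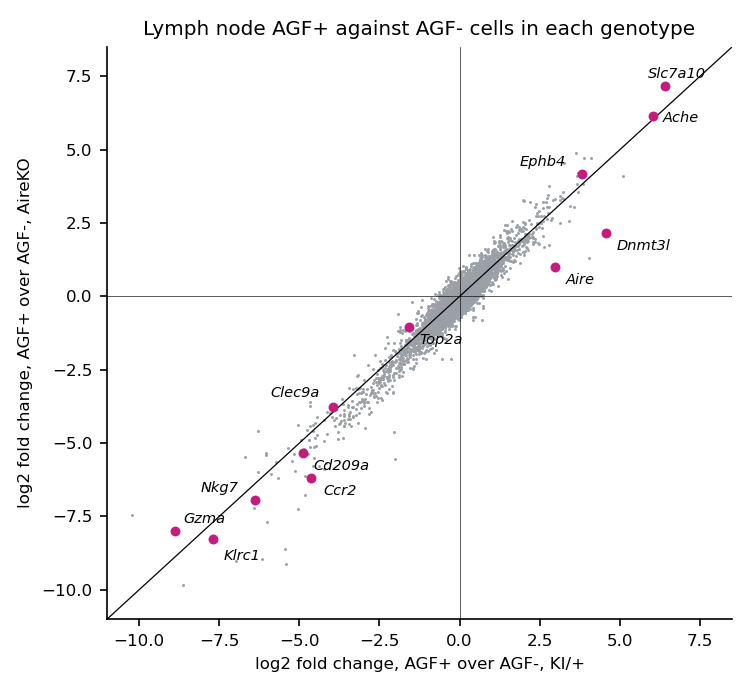
Fitted log2 fold change of AGF+ against AGF− lymph node cells in KI/+ (x axis) and AireKO mice (y axis), with 1 point per gene for the 11012 genes of average log2 CPM of at least 3 and the diagonal drawn as a line. Points follow the diagonal (r = 0.95), and Aire and Dnmt3l lie below it, at 2.99 and 4.58 in KI/+ against 0.99 and 2.15 in AireKO.

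Whether loss of Aire changes the AGF+ cells of the lymph node was asked by comparing AireKO with KI/+ AGF+ cells. Aire (-2.19 ± 0.15, adjusted p = 8.6e-06) and Dnmt3l (2.73 ± 0.23, adjusted p = 1.1e-04) were the 2 genes of 15884 that passed. At an unadjusted p under 0.05 there were 583, or 3.67% of genes, below the 0.05 share that chance gives. The replicate block gave 1098 genes at that unadjusted bound and limma voom 2474. After adjustment DESeq2 called 4 genes and limma voom 2. For 92.5% of the 11012 genes with an average log2 CPM of at least 3 the 95% interval of the change lay inside 2-fold. Between genotypes 10.3% of genes did not overlap (chance 10% for independent libraries). Libraries of the same number deviated together, so that chance share is not exact here. Fn1, fibronectin, named here after its values were seen, stood at 6.36 ± 2.29 CPM in KI/+ and 0.778 ± 0.255 CPM in AireKO cells. It did not pass the main test (-3.01 ± 0.46, adjusted p = 0.0607). DESeq2 called it (-3.05, adjusted p = 3.4e-05), as did the fit with the replicate number as a block (-2.999, adjusted p = 0.0198). So did library size alone, the fit of only the groups compared and that without KI/+ replicate 2. Limma voom, DESeq2 size factors, glmTreat and the fit of all libraries did not. Mature DC genes leaned lower in AireKO cells (median log2 fold change -0.32 over 32 members, camera adjusted p = 3.8e-08), but adjusted p = 0.582 with an estimated correlation. Of its members 0 passed over all genes against 2 adjusted over the list alone. Its member with the smallest p, Il12b, the p40 chain of interleukin-12, had -2.06 ± 0.39 (adjusted p = 0.430, 0.0223 with DESeq2). Markers of cDC1 cells leaned lower by as much (median -0.31, 0 of 18 passing, 0 adjusted over the list alone, camera adjusted p = 0.00268, adjusted p = 0.576 with an estimated correlation). Cytokines and NF-kB genes, which share members with the mature DC list, did so too (medians -0.29 and -0.14, 0 of 14 and 0 of 21 passing, 1 and 0 adjusted over the list alone). Their camera adjusted p were 0.00337 and 0.0117, and 0.576 and 0.809 with an estimated correlation. Mitochondrially encoded genes leaned higher in the same AireKO libraries (median 0.38, 0 of 7 passing, 0 adjusted over the list alone, camera adjusted p = 0.00285, adjusted p = 0.682 with an estimated correlation). They took 1.53 ± 0.0724% of counts there and 1.19 ± 0.183% in KI/+. Cholesterol synthesis genes had 0 of 20 members passing (0 adjusted over the list alone) and a lower median of -0.21. Cholesterol synthesis genes had camera adjusted p = 6.0e-04, and adjusted p = 0.576 with an estimated correlation.

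Camera called 6 of 31 lists between genotypes in AGF+ cells and none remained with an estimated correlation or with fry. The replicate block gave 4 genes, adding Fn1 and Capn11, a calpain protease, also named after its values were seen (-5.12, adjusted p = 7.1e-04). Its fall rested on KI/+ replicates 1 and 3, at 8.07 and 13.8 CPM, as KI/+ replicate 2 had 0.153 CPM and the AireKO libraries 0 to 0.336 CPM. Without KI/+ replicate 2 of these cells the count was 7, and with no filter on low counts 97, of which 93 were genes also tested with the filter.

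In lymph node AGF− cells Dnmt3l was the 1 gene called between genotypes (5.16 ± 0.42, adjusted p = 1.0e-04). It rose from 0.445, 0 and 0.636 CPM in KI/+ to 10.3, 16.5 and 13.8 CPM in AireKO libraries. Mature DC genes had the smallest camera p of all lists, with a median of -0.60 over 32 members (camera adjusted p = 1.8e-21), adjusted p = 0.297 with an estimated correlation. Over all genes 0 members passed and 6 fell when adjusted over the list alone. Its members with the smallest p, none of which passed over all genes, were Il12b (-2.16 ± 0.39, adjusted p = 0.575), Anxa3, an annexin (-0.76 ± 0.21), Socs2, a suppressor of cytokine signalling (-1.07 ± 0.34), and Ccr7, the chemokine receptor that guides DCs to lymph nodes (-0.95 ± 0.30). Il12b was called by DESeq2 (-2.17, adjusted p = 0.0186) and in the fit without AireKO replicate 2 of these cells (adjusted p = 0.0407). Markers of cDC1 cells leaned lower here too (median -0.27, 0 of 18 passing, 1 adjusted over the list alone, camera adjusted p = 0.00221, adjusted p = 0.433 with an estimated correlation). Cholesterol synthesis genes leaned the same way (median -0.39, 0 of 20 passing, 0 adjusted over the list alone, camera adjusted p = 1.2e-08, adjusted p = 0.297 with an estimated correlation), where the members with the smallest p were Cyp51 (log2 fold change -0.71 ± 0.20) and Sqle (-0.64 ± 0.21). B cell markers leaned higher in AireKO cells (median 0.56, 0 of 15 passing, 0 adjusted over the list alone, camera adjusted p = 1.4e-06, adjusted p = 0.433 with an estimated correlation). Immunoglobulin and T cell receptor genes took 0.123, 0.191 and 0.140% of counts in the KI/+ and 0.118, 0.164 and 0.493% in the AireKO libraries of AGF− cells, so the higher AireKO mean came from its replicate 3.

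The AGF− comparison tested 15884 genes, with 949 at an unadjusted p under 0.05, or 5.97%, where chance gives a share of 0.05. The replicate block had 1422 genes at that unadjusted bound and limma voom 645. After adjustment DESeq2 made 3 calls and limma voom 1. Of the 11012 genes with an average log2 CPM of at least 3, 90.7% had intervals inside 2-fold. Camera called 11 of 31 lists, 6 higher and 5 lower in AireKO cells, and none remained with an estimated correlation or with fry. The count depended on 1 library: without AireKO replicate 2 of these cells 89 genes were called, 7 higher and 82 lower in AireKO, while 1 was called without the libraries numbered 2 of every group. The count was 0 with only these 6 libraries in the fit (Dnmt3l 5.14, adjusted p = 0.0920), 270 with no filter on low counts (246 of them also tested with the filter), and 2 with the replicate block, which added Capn11 (-5.80, adjusted p = 0.00304). Here Capn11 stood at 5.57 and 9.12 CPM in KI/+ replicates 1 and 3, at 0 in KI/+ replicate 2 and at 0 to 0.195 CPM in AireKO.

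The interaction of genotype and sort tests whether the change with loss of Aire differs between AGF+ and AGF− cells. Aire was the 1 gene of 15884 that passed (-1.998 ± 0.22, adjusted p = 0.00451). At an unadjusted p under 0.05 there were 261, or 1.64%, fewer than chance gives. Limma voom had 478 genes at that unadjusted bound and the replicate block 477. The difference for Dnmt3l, -2.42 ± 0.57, did not pass (adjusted p = 1.0). Fn1 did not pass (adjusted p = 0.0922). It was added by DESeq2 (-3.55, adjusted p = 3.6e-05) and with the replicate block (-3.50, adjusted p = 0.0292), for 2 calls in each. It was also added when AireKO AGF− replicate 1 was left out (-3.69, adjusted p = 0.0308), again for 2 calls. Without the libraries numbered 2 of every group the interaction of Aire was -2.02 and no longer passed (adjusted p = 0.674). Across 11012 genes the changes with genotype in AGF+ and AGF− cells correlated (r = 0.44, rho = 0.39); genes are not independent replicates, and libraries of the same number deviated together across sorts.

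In bone marrow the AGF+ cells of KI/+ mice were compared with total DCs, which came from another gate. AGF+ cells lay in the B220−CD24+ population low in or lacking CD11b, total DCs in the B220−CD11c+MHCII+ population, so sort and gate cannot be separated and genes of the gates are no finding. Among the largest rises were Dntt, which adds nucleotides during V(D)J recombination (642-fold, counting interval 177 to 5303), Hoxa9, a homeobox factor of haematopoietic progenitors (353-fold, counting interval 97.4 to 2921), and Lax1, a lymphocyte adaptor (392-fold, counting interval 70.0 to 15522). The others were Nfasc, neurofascin (1459-fold, counting interval 262 to 57681), Ache (at least 69.7-fold), Cacna1h, a T-type calcium channel (at least 89.4-fold), Slc6a7, a proline transporter (314-fold, counting interval 56.0 to 12447), and Shisa2 (at least 76.3-fold). Aire rose by 6.61 ± 0.31 and Icosl by 3.39 ± 0.14, and Dnmt3l was 40.6-fold (counting interval 13.6 to 199.6) higher. Among the largest falls were Mpo, myeloperoxidase (lower 275-fold, counting interval 75.6 to 2273), Cd209a (log2 fold change -6.99 ± 0.79), Fcgr1 (-5.64 ± 0.44), Asgr2 (-6.23 ± 0.57), Flnc (-5.62 ± 0.52), Pilra (-5.25 ± 0.55) and Cd209c (-5.27 ± 0.89), and Snhg7os (lower 127-fold, counting interval 43.2 to 619.9). Cd209a and Cd209c belong to a family of near copies.

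Lymphoid markers rose as groups. For B cells 12 of 14 measured members rose and 1 fell (12 rose when adjusted over the list alone), with Igkc (log2 fold change 5.29 ± 0.33), Blk (4.27 ± 0.29) and Cd79b (2.41 ± 0.16). B cell markers had camera adjusted p = 6.9e-11, and adjusted p = 0.0491 with an estimated correlation. For T and NK cells 7 of 8 measured members rose (7 rose when adjusted over the list alone), among them Lck (log2 fold change 5.43 ± 0.39), Tcf7 (2.699 ± 0.36) and Lef1 (1.77 ± 0.19). T and NK cell markers had camera adjusted p = 9.8e-05, and adjusted p = 0.0608 with an estimated correlation. Of the plasmacytoid DC genes 11 of 16 measured members rose and 2 fell (12 rose when adjusted over the list alone), including Spib (log2 fold change 3.07 ± 0.25), Runx2 (2.57 ± 0.14) and Ccr9 (2.02 ± 0.16). Plasmacytoid DC genes had camera adjusted p = 1.1e-07, and adjusted p = 0.0755 with an estimated correlation. Of the genes of group 3 innate lymphoid cells 6 of 12 measured members rose and 2 fell (7 rose when adjusted over the list alone), such as Cxcr5 (log2 fold change 3.37 ± 0.17), Il1r1 (3.17 ± 0.15) and Kit (1.48 ± 0.14). Innate lymphoid genes had camera adjusted p = 2.4e-04, and adjusted p = 0.0608 with an estimated correlation. Of the progenitor genes 8 of 13 measured members rose and 1 fell (10 rose when adjusted over the list alone), with Flt3 (log2 fold change 3.15 ± 0.26) and Meis1 (2.64 ± 0.15). Progenitor genes had camera adjusted p = 6.2e-07, and adjusted p = 0.0755 with an estimated correlation. Of the cell cycle genes 25 of 26 measured members rose (25 rose when adjusted over the list alone), for example Foxm1 (log2 fold change 1.96 ± 0.23) and Plk1 (1.63 ± 0.19). Cell cycle genes had camera adjusted p = 9.0e-08, and adjusted p = 0.410 with an estimated correlation.

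Of the monocyte and macrophage markers 13 of 16 measured members fell and 2 rose (13 fell when adjusted over the list alone), with C1qa (log2 fold change -3.96 ± 0.34) and Adgre1 (-3.06 ± 0.18). Monocyte and macrophage markers had camera adjusted p = 8.3e-10, and adjusted p = 0.173 with an estimated correlation. Of the cDC2 markers 11 of 14 measured members fell and 1 rose (11 fell when adjusted over the list alone), where Clec12a (log2 fold change -4.98 ± 0.41) and Mgl2 (-2.82 ± 0.26) fell and Esam (log2 fold change 3.14 ± 0.33) rose. Markers of cDC2 cells had camera adjusted p = 3.1e-06, and adjusted p = 0.0755 with an estimated correlation. The member Itgam encodes the CD11b of the gate. Of the innate sensors 17 of 25 measured members fell and 3 rose (17 fell when adjusted over the list alone), among them Tlr4 (log2 fold change -3.65 ± 0.35) and Tlr6 (-2.01 ± 0.22). Innate sensors had camera adjusted p = 4.3e-05, and adjusted p = 0.130 with an estimated correlation. Of the genes of eosinophils, basophils and mast cells 9 of 11 measured members fell and 1 rose (9 fell when adjusted over the list alone), with Cd200r3 (log2 fold change -4.66 ± 0.75) and Gata2 (-3.08 ± 0.53). Eosinophil, basophil and mast cell genes had camera adjusted p = 0.0117, and adjusted p = 0.319 with an estimated correlation. Of the nuclear genes of the respiratory chain 17 of 20 measured members fell and 1 rose (17 fell when adjusted over the list alone), including Atp5a1 (log2 fold change -0.67 ± 0.11). Respiratory chain genes had camera adjusted p = 1.7e-04, and adjusted p = 0.345 with an estimated correlation. Of the mitochondrially encoded genes 7 of 10 measured members fell (7 fell when adjusted over the list alone), and they took 2.74 ± 0.172% of counts in AGF+ cells and 3.47 ± 0.158% in total DCs. Mitochondrial genes had camera adjusted p = 0.0117, and adjusted p = 0.512 with an estimated correlation.

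In total 3531 genes were higher and 3350 lower in bone marrow AGF+ cells of 15503 tested, 2205 and 1328 at least 2-fold, and 51.5% did not overlap (chance 10%). With library size alone in place of TMM the split was 4241 higher to 2642 lower, 61.6% against 51.3% of calls, and the median of all genes moved by 0.11 (log2), so these changes are relative to the TMM scale. Without the libraries numbered 2 the count was 3858 in place of 6881. Camera called 12 of 31 lists, 6 higher and 6 lower, and only the B cell list remained with an estimated correlation. Fry called 21 lists.

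In bone marrow AGF+ cells the same pair of genes passed between genotypes as in the lymph node. Dnmt3l rose by 3.63 ± 0.24 (adjusted p = 1.5e-04) and Aire fell by 2.81 ± 0.22, the 2 calls of 15503 genes. At an unadjusted p under 0.05 there were 259, or 1.67%, fewer than chance gives. Limma voom had 860 genes at that unadjusted bound and the replicate block 425. After adjustment DESeq2 and limma voom made 2 calls each. Of the 10569 genes with an average log2 CPM of at least 3, 95.6% had an interval inside 2-fold. Of all genes tested 6.70% did not overlap (chance 10% for independent libraries, which those of the same number were not). Interferon response genes leaned lower in AireKO cells, with 0 of 24 members passing and 0 adjusted over the list alone (median -0.26, camera adjusted p = 6.9e-05, adjusted p = 0.736 with an estimated correlation). Mitochondrially encoded genes leaned higher, with 0 of 10 passing and 0 adjusted over the list alone (median 0.29, camera adjusted p = 2.1e-06, adjusted p = 0.461 with an estimated correlation). Without the libraries numbered 2 Aire no longer passed (-2.67, adjusted p = 0.161), and with no filter on low counts 26 genes did, 25 of them also tested with the filter. Camera called 5 lists, 8 with the replicate block, chosen after the data were examined, and none with an estimated correlation.

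Whether the change with genotype differs between the tissues was tested by an interaction over all libraries. For Aire the difference was 0.64 ± 0.26 (adjusted p = 1.0) and for Dnmt3l -0.88 ± 0.34 (adjusted p = 1.0). EdgeR called 0 of 17265 genes, with 456 at an unadjusted p under 0.05, or 2.64%, fewer than chance gives. That shortfall depended on the method, as limma voom had 1724 genes at that unadjusted bound and the replicate block 662. After adjustment DESeq2 and limma voom called 0 and 0. With no filter on low counts edgeR called 17, 17 of them also tested with the filter. Changes with genotype in lymph node and bone marrow AGF+ cells showed no common trend across 9774 genes (r = -0.02, rho = -0.07).

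AGF+ cells of KI/+ mice differed widely between the tissues, compared over all libraries. Cycling was the clearest contrast: all 26 measured cell cycle genes were lower in lymph node than in bone marrow AGF+ cells (26 adjusted over the list alone, camera adjusted p = 6.8e-37, adjusted p = 0.0751 with an estimated correlation), among them Cenpf (log2 fold change -5.83 ± 0.34), Top2a (-4.95 ± 0.26) and Ccnb2 (-4.84 ± 0.25). All 20 cholesterol synthesis genes were lower as well (20 adjusted over the list alone, camera adjusted p = 2.0e-10, adjusted p = 0.131 with an estimated correlation), such as Idi1 (log2 fold change -3.23 ± 0.27), Sqle (-2.33 ± 0.19) and Hmgcs1 (-2.02 ± 0.18). So were all 10 measured mitochondrially encoded genes (10 adjusted over the list alone, camera adjusted p = 3.3e-04, adjusted p = 0.426 with an estimated correlation), at 1.19 ± 0.183% of counts in lymph node and 2.74 ± 0.172% in bone marrow. Of the innate sensors 13 of 25 measured members rose and 1 fell (13 rose when adjusted over the list alone), with Tlr11 (log2 fold change 5.14 ± 0.35), Tlr5 (4.07 ± 0.23) and Tlr1 (4.06 ± 0.22). Innate sensors had camera adjusted p = 1.9e-05, and adjusted p = 0.116 with an estimated correlation. Of the progenitor genes 11 of 14 measured members fell and 1 rose (11 fell when adjusted over the list alone), including Ly6a (log2 fold change -5.56 ± 0.74) and Meis1 (-2.50 ± 0.19). Progenitor genes had camera adjusted p = 0.00158, and adjusted p = 0.131 with an estimated correlation. Of the plasmacytoid DC genes 11 of 16 measured members fell and 2 rose (11 fell when adjusted over the list alone), with Ly6d (log2 fold change -4.28 ± 0.48) and Tcf4 (-1.85 ± 0.15). Plasmacytoid DC genes had camera adjusted p = 0.00781, and adjusted p = 0.724 with an estimated correlation. No difference in Aire passed between these cells (0.17 ± 0.17, adjusted p = 0.401).

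The largest rises in lymph node AGF+ cells were Ehf, an epithelial ETS factor (at least 83.0-fold), Lyz1 (at least 50.05-fold), Ankrd34a (log2 fold change 8.41 ± 0.44), Bank1, a B cell scaffold protein (at least 36.9-fold), Cntn1, contactin 1 (275-fold, counting interval 49.0 to 10902), Adgrl3, a latrophilin (at least 21.3-fold), and Cd209d and Cd209b (at least 26.1-fold and at least 20.1-fold). The largest falls were Dntt (at least 507-fold lower), Gzmb (at least 379-fold), Klk1b11 (at least 277-fold), Krt24, a keratin (at least 238-fold), Ccn3 (at least 217-fold), Calcb, a calcitonin gene-related peptide (at least 215-fold), AF067061 (1192-fold, counting interval 214 to 47138) and Ccl24 (log2 fold change -9.49 ± 0.44), eotaxin 2. Reads of Lyz1, of the Cd209 family and of Klk1b11 can be shared with close paralogs. Mature DC genes split in direction: 13 of 32 measured members rose and 12 fell (14 rose when adjusted over the list alone), and Ccl17 (log2 fold change -5.997 ± 0.36), Pdcd1lg2 (-4.90 ± 0.20) and Ccl22 (-3.23 ± 0.37) were lower and Ccl5 (log2 fold change 2.42 ± 0.35) higher in the lymph node. Mature DC genes had camera adjusted p = 0.663, and adjusted p = 0.951 with an estimated correlation.

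Lymph node AGF+ cells had 4694 genes higher and 4671 lower than bone marrow AGF+ cells of 17265 tested, 2624 and 2699 at least 2-fold, and 61.4% did not overlap (chance 10%). With library size alone the median of all genes moved by 0.16 (log2) and 59.9% of calls were higher, against 50.1%, and over all alternatives this share ran from 46.2% to 59.9%. Camera called 13 of 32 lists, 2 higher and 11 lower, and none with an estimated correlation, while fry called 21. The gates of the tissues differed, so tissue and gate cannot be separated.

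**Figure D5:**
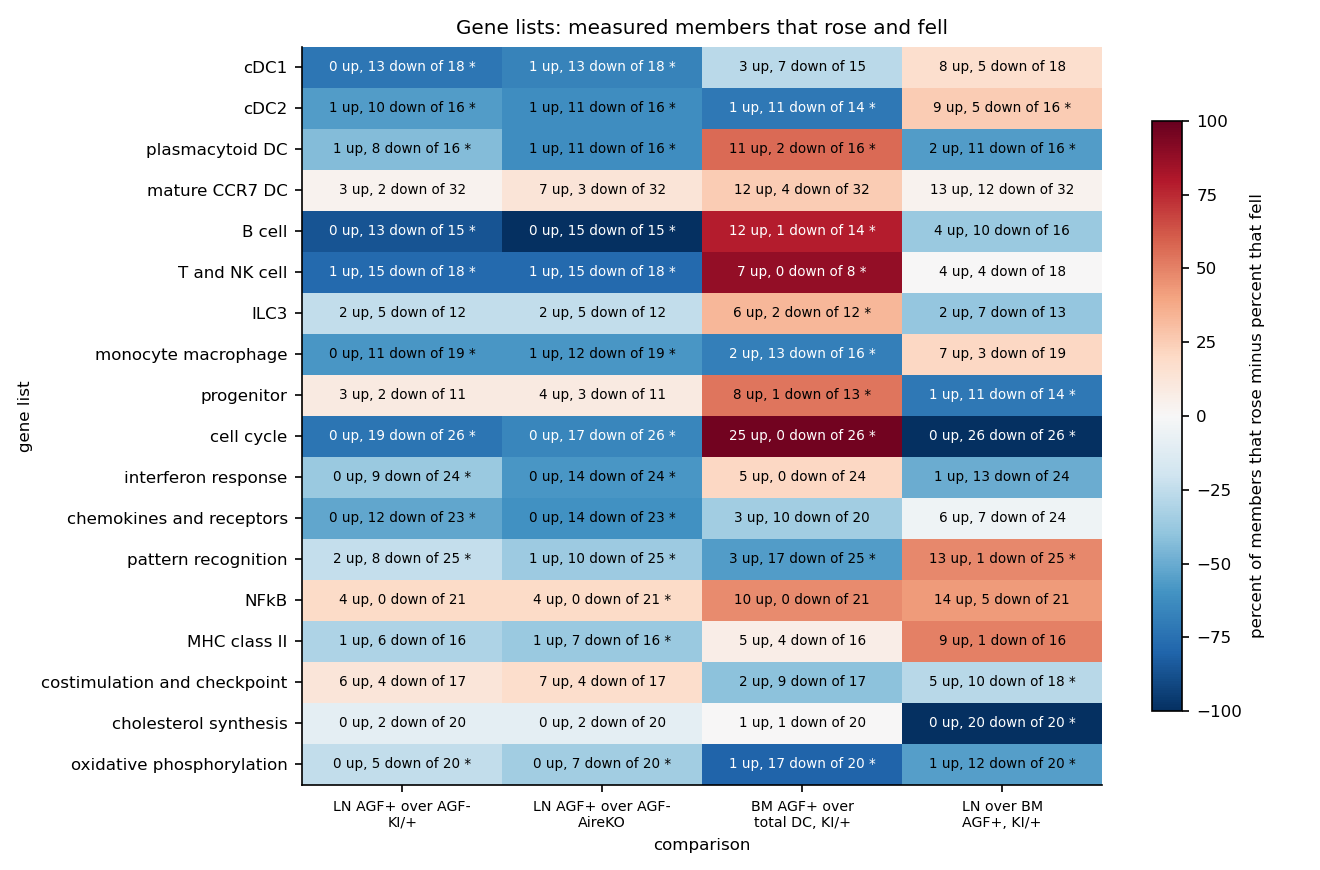
Gene lists (one per line) in the comparisons (columns): text gives how many measured members rose and fell, colour the percent that rose minus the percent that fell, and an asterisk a camera adjusted p under 0.05. Cell cycle genes rose in bone marrow AGF+ cells (25 of 26) and fell in lymph node AGF+ cells (19 of 26).

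Part of what set AGF+ cells apart from the DCs they were compared with was common to both tissues. In bone marrow sort and gate cannot be separated, so the shared genes are not tied to the reporter alone. Among 14325 genes tested in both, 740 were higher in AGF+ cells of lymph node and of bone marrow, where independent lists give 299 (Fisher's exact test over genes, p = 1.3e-167), and 685 were lower in both, where they give 322 (p = 3.3e-110). Opposite calls were made for 106 genes higher in the lymph node and lower in bone marrow, and for 324 the other way. Bone marrow called 3090 of the 14325 genes higher and 3092 lower, so independent lists give nearly the same 299 and 322 for opposite calls. Only the 106 lay below this. Ache and Dnmt3l rose in both. Fold changes correlated weakly across 9774 genes (r = 0.30, rho = 0.35), and genes are not independent replicates.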

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

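Of the tests in this part, the fit without the libraries numbered 2 and the count of groupings that part the genotypes in both sorts were chosen after their results were seen, and the others were set before. What drew attention here is a change with loss of Aire that differs between AGF+ and AGF− cells of the lymph node, or between AGF+ cells of the tissues, by a test of the difference itself.

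The change of Aire with genotype differed by -1.998 ± 0.22 (log2) between AGF+ and AGF− cells (adjusted p = 0.00451). It was the only gene to pass that test. Without the libraries numbered 2, which leaves fewer samples, the difference was as large (-2.02 ± 0.29) but no longer passed (adjusted p = 0.674, against 8.5e-10 to 0.0397 over its other alternatives). Lists differed by camera as well. Relative to AGF− cells, AGF+ cells leaned lower with loss of Aire for Aire locus neighbours (camera adjusted p = 0.0369), cDC2 markers (0.00637), B cell markers (0.00464) and immediate early and heat shock genes (0.0365), and higher for mature DC genes (0.00220) and cell cycle genes (0.00637). With an estimated correlation these were lost, at 0.578 for cDC2 markers and 0.807 for the others. Of 50 groupings of the libraries, the real one among them, 8 gave at least the real one's 1 call, and the highest gave 142. This share overstates chance, since 6 of the 7 others with a call keep the real genotypes of the AGF+ libraries. Of the 37 that part the genotypes in both sorts 1 had calls, a share of 0.0526 with the real grouping added, so chance is not excluded. The highest count points to a structure of the samples. Its grouping set libraries numbered 3 against those numbered 2 in both sorts, where a shared difference cancels, and the KI/+ library numbered 1 against the AireKO one in opposite order in the sorts, where it does not. Which libraries gave the calls was not tested.

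Between the tissues, AGF+ cells of the lymph node leaned lower than those of bone marrow in their change with loss of Aire for mature DC genes (camera adjusted p = 2.1e-05) and cholesterol synthesis genes (0.00291), and higher for interferon response genes (0.0200). All were lost with an estimated correlation (adjusted p = 0.854), and no gene passed in this interaction.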

How the results depend on the processing

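Of the tests in this part, the fit without the libraries numbered 2, the offsets for gene length and GC content and the block for lists were chosen after the data were examined, and the others were set before. No called gene that is named took the opposite direction under the alternatives run for it, and no list was called in opposite directions. Which direction held more calls did turn. In the lymph node reporter comparison of KI/+ mice 47.9% of calls were higher, but 53.5% with library size alone and 52.8% with the offsets, and in AireKO 46.2% against 52.0% with the offsets. Between tissues the share was 50.1%, and it lay on the other side of even in 14 of 17 alternatives, the cause untested. Of 9200 values of named genes 8885 kept their side of the threshold and 315 lost it, and of 843 list results 688 kept it, 117 lost it and 38 gained it. At an adjusted p under 0.01 the share of calls with the same sign in the comparison they were set against moved by more than its counting interval in 3 of 9 cases and took the other side of even in 0; that share was tried under no other alternative. Stricter tests left fewer calls: glmTreat 1306 and 1629 in the lymph node reporter comparisons (KI/+, AireKO), 3212 in bone marrow and 5216 between tissues, and an adjusted p under 0.01 1812 and 2333 in the lymph node, with shared calls of 690 and 851 between genotypes and 370 and 319 between tissues.

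The few calls of the genotype comparisons moved most, and the cause was not tested. With no filter on low counts there were 97 in lymph node AGF+ cells, 270 in AGF− cells, 14 in their interaction, 26 in bone marrow and 17 in the tissue interaction. Of these 93, 246, 13, 25 and 17 were genes also tested with the filter, so genes that the filter removes are not their main source. DESeq2 gave 4, 3 and 2 in the first 3, the replicate block 4, 2 and 2, and a fit of only the groups compared 0 in AGF− cells. Elsewhere within a tissue the block moved counts by less than 1.5 times, to 4338 and 4969 in the lymph node reporter comparisons, 7633 for the reporter and 2 for genotype in bone marrow. It changed no call of a gene named by the rule, and of the lists it added 14 calls and ended 1. Between tissues, where the pairing check was not met for the cells compared, it gave 9859 calls against 9365, and 0 in the interaction. Without the libraries numbered 2, which leaves fewer samples, 1942 genes were called in the KI/+ lymph node reporter comparison, 3858 in bone marrow, 0 in the lymph node interaction and 1 for genotype in bone marrow.

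With 1 library left out, calls ranged over 2271 to 2923 and 2874 to 4126 in the lymph node reporter comparisons, 2 to 7 and 1 to 89 for genotype in AGF+ and AGF− cells, 1 to 2 in their interaction, 5672 to 7550 and 2 to 2 for reporter and genotype in bone marrow, 0 to 0 in the tissue interaction and 8060 to 8932 between tissues. With an estimated correlation 2 lists remained in each lymph node reporter comparison, 1 in the bone marrow one and 0 elsewhere. Fry gave 0 in the genotype and interaction comparisons. It gave 16 and 17 in the lymph node reporter comparisons (KI/+, AireKO), 21 in the bone marrow one and 21 between tissues. The block gave 8 for genotype in bone marrow. The cause was not tested for lists. At this depth a gene at 1 CPM has 3.91 to 6.56 counts in a library, which limits what can be said about genes below it.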

Other observations

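Of the tests in this part, those of Dnmt3l, of the genes higher in lymph node AGF+ cells, of the few genotype calls, of the need for Aire and of genes with at least 3 counts, and the separate count of splits of an interaction, were chosen after the result was seen. The other counts of splits, the test of female mice and that of genes detected were written before.

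A set of 738 genes other than Aire and Dnmt3l was higher in AGF+ cells of both tissues in KI/+ mice. Chosen after their values were seen, Sema3f, Rimkla, Fgfr3, a fibroblast growth factor receptor, and Colq, which anchors acetylcholinesterase, rose with Ache, by 3.67 ± 0.46, 3.27 ± 0.41, 3.14 ± 0.22 and 2.91 ± 0.21 in lymph node and by 5.55 ± 0.46, 4.63 ± 0.35, 4.14 ± 0.17 and 6.48 ± 0.28 in bone marrow. In the lymph node AGF+ cells of KI/+ mice were lower in immediate early and heat shock genes, where 5 of 20 measured members fell (5 fell when adjusted over the list alone), with Egr2 (log2 fold change -3.08 ± 0.47), Nr4a1 (-2.16 ± 0.37) and Klf2 (-2.08 ± 0.19). Immediate early and heat shock genes had camera adjusted p = 0.00526, and adjusted p = 0.534 with an estimated correlation. Of the genes of actin and migration 11 of 21 measured members fell and 1 rose (12 fell when adjusted over the list alone), with Coro1a (log2 fold change -0.98 ± 0.19) and Vim (-0.78 ± 0.16). Actin and migration genes had camera adjusted p = 1.7e-04, and adjusted p = 0.309 with an estimated correlation.

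Of 24 tissue antigens listed beforehand as dependent on Aire in the thymus 23 were matched, and too few passed the expression filter to be tested. Whether each listed gene depends on Aire was not checked here. Together they drew 0 to 2 counts per library in lymph node AGF+ cells of KI/+ mice and 1 to 8 in AireKO, 1 to 2 and 3 to 30 in AGF− cells, 9 to 11 and 7 to 20 in bone marrow AGF+ cells and 1 to 2 in total DCs. Capn11, on chromosome 17, had 5.57 to 13.8 CPM in the 8 KI/+ libraries numbered 1 or 3, 0 to 0.384 CPM in the 4 numbered 2 and 0 to 0.429 CPM in the 9 AireKO libraries. Slc15a2, on chromosome 16, had 13.9 to 50.3, 0 to 0.617 and 3.83 to 53.5 CPM; both were chosen after their values were seen.

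Why Dnmt3l is higher in AireKO cells was weighed. Reads from the Aire exon that overlaps Dnmt3l are argued against as the source as far as they follow Aire as a whole. Dnmt3l rose by 2.73 while Aire changed by -2.19 in lymph node AGF+ cells. Reads in the shared exon were not counted apart, so whole-gene counts cannot exclude this source. A response to the lower level of counts to the whole Aire gene is argued against by AGF− cells, where Dnmt3l rose by 5.16 with Aire at -0.19. The KI/+ side of that rise holds 2, 0 and 3 Dnmt3l counts. Which part of Aire each allele lacks is not given in the sources used here. Whole-gene counts therefore cannot show whether intact Aire transcript was unchanged in AGF− cells, and a response to its loss is not excluded. A change carried by the null allele itself, such as transcription running from the altered locus into Dnmt3l, could give a rise of at least 2.73 in every AireKO group, and these data cannot tell it from an effect of lost Aire protein. In CPM, Dnmt3l gained 51.5, 13.2 and 94.8 where Aire lost 88.9, 1.71 and 86.9 (lymph node AGF+, AGF−, bone marrow AGF+).

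The 894 genes at least 2-fold higher in lymph node AGF+ cells of KI/+ mice were weighed next. Gene length or GC content is argued against, as 99.3% of them were still called with offsets for both. Dilution of DC transcripts by other cell types in the AGF− sort, whose markers were higher there, would raise DC genes in general. A general rise of 2-fold was not seen in the mature DC list, whose median was 0.02 and upper quartile 0.36. The lower quartile of 1.28 of the 894 genes adds nothing, since they were picked at 2-fold or more. The mature DC list covers only that state. Markers of cDC1 and cDC2 cells and MHC class II genes did not rise as lists either, and most cDC1 and cDC2 markers fell. The subset markers also depend on which DC subsets each sort held, so dilution is not excluded for other DC genes. A difference in kind between AGF+ and AGF− DCs stays possible but was not tested, and sorted bulk libraries cannot show which cells carry it.

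The few genotype calls were weighed last. A mislabelled library is argued against by Aire, at most 26.6 CPM in AireKO and at least 79.6 CPM in KI/+ AGF+ cells. In lymph node AGF+ cells 92.5% of intervals lay inside 2-fold, over the 11012 genes with an average log2 CPM of at least 3. This argues against too little precision for 2-fold changes in those genes, not in lower ones. On simulated counts of this layout 69 of 100 2-fold changes were recovered, and smaller or rarer changes could be missed. Spread added by 1 library stays open in AGF− cells: 89 genes were called without AireKO replicate 2 and 1 with it, but that removal leaves a library numbered 2 in KI/+ alone, and removing these from every group gave 1. The first count alone met the bound set for this explanation, and the second was added to its verdict after both were seen. A small effect of Aire on these cells at steady state stays possible.

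The hypothesis that the libraries numbered 2 came from female mice predicted higher levels of the X-linked genes Kdm6a, Kdm5c, Eif2s3x and Ddx3x, which escape inactivation. They were higher in the library numbered 2 in 7 of 7 groups (median log2 ratio 0.41, exact sign test p = 0.0156), so the data fit female mice and not the label. The groups share these numbers, so the 7 are not independent if the same mice gave several groups.

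A second hypothesis was that loss of Aire lowers the number of genes detected at equal depth. The difference was -330 genes in lymph node AGF+ cells (22948 ± 101 in AireKO, 23278 ± 512 in KI/+, exact permutation p = 0.5, smallest possible 0.1) and 60.3 in bone marrow (exact permutation p = 0.9). Counting genes with at least 3 counts at that depth, a second measure of the same libraries, every AireKO library of lymph node AGF+ cells (18158 to 18403) lay below every KI/+ library (18473 to 19003, exact permutation p = 0.1), while the ranges overlapped in bone marrow (18287 to 18432 and 17961 to 18419, exact permutation p = 0.8). The bound written beforehand, overlapping ranges of genes detected in both tissues, was met and would have counted against the hypothesis. It was a poor bound, because overlapping ranges of 3 libraries do not exclude a difference, and the verdict was changed to cannot tell after the result was seen, so the question stays open. Bone marrow AGF+ cells had 23164 ± 264 genes detected against 21727 ± 222 in total DCs (exact permutation p = 0.1).

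The last hypothesis, that the genes higher in AGF+ cells of both tissues need Aire, is argued against. Their median change in AireKO cells was -0.0877 in lymph node (quartiles -0.24 to 0.04) and 0.01 in bone marrow, and 623 of 738 were still called higher in AGF+ cells of AireKO lymph nodes. The genes were picked in KI/+ libraries that also serve as the reference here, which pulls these medians down.

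Splitting the same libraries into other groups of the same sizes gave as many calls as the real grouping only in the real grouping itself, 1 of 10, in both lymph node reporter comparisons, genotype in AGF+ cells of either tissue, the bone marrow reporter comparison and the tissue comparison, with 0 calls at most in any other split. Genotype in AGF− cells gave 4 of 10 against its 1 call, with 3 at most. A set of 10 splits cannot give a share under 0.05. The interaction with sort gave 8 of 50 against its 1 call, with 142 at most, but 6 of the 7 other groupings with a call keep the real genotypes of the AGF+ libraries, so this share overstates chance. Without the groupings that keep the genotypes of a sort it was 0.0526, and chance is not excluded. The interaction with tissue has a real count of 0, which all 50 of 50 groupings reach whatever they call (highest 0), so its splits test nothing, and that verdict was changed after they were seen.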
